A study of Mus musculus with 2 samples.

How the data were processed

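The study compared gene expression in a pair of natural killer (NK) cell populations from the liver of untreated B6 wild-type mice. Both populations were sorted by flow cytometry as cells that carry NK1.1 and lack CD3, per the labels' protocols. They differ in binding of the antibody DX5, which recognises the integrin alpha 2 chain (Itga2, also called CD49b). Total RNA of each population was converted to biotin-labelled cRNA and hybridised to an Affymetrix mouse expression array. There was 1 array for DX5- NK cells and 1 array for DX5+ NK cells, so n = 1 in each group. The number of mice behind each array is not given in the sources used here.

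The deposited table held 1 intensity per probe set and array for 45101 probe sets, 64 of them control probe sets. The authors made these intensities with MAS5, per the submitters' processing notes; MAS5 combines the probes of a probe set into 1 linear signal and scales each array by 1 factor. Software version and settings are not given in the sources used here. The values were linear, ranged from 0.1 to 43870 and had no zeros. After leaving out the lowest and highest 2% of probe sets the mean intensity was 499.8 on both arrays, so both arrays share a scaling target. The table carried no detection calls, no scanner values and no bead or pixel spread, so the precision of a single intensity is unknown and the number of arrays limits what can be compared.

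Probe sets were named from an annotation table of the array platform. It listed 35890 probe sets, of which 34958 had 1 gene symbol and 932 had several; the other 9211 are unnamed here. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, in which 34754 matched and none had to be renamed. Probe sets with several genes were not used to name a gene. No coordinates are printed, since no genome build belongs to the intensities. Each gene was represented by the probe set with the highest mean log2 intensity over both arrays, which gave 18193 genes.

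All values were taken to log2 as deposited, with no offset and no further scaling. The log2 ratio is DX5- minus DX5+. A detection limit was set per array at the 95th percentile of 148 probe sets for gene families with little expected use in lymphocytes or liver (olfactory, vomeronasal and taste receptors, keratin-associated proteins, crystallins and opsins). It was 90.9 intensity units on the DX5- array and 107 on the DX5+ array. Genes below the limit on both arrays were left out. Where a gene was above the limit on 1 array only, its value on the other was set to that array's limit, and the resulting fold is a lower bound, written "at least". A bound that fell on the wrong side was set to a ratio of 1.

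With 1 array per group there is no spread between samples, so no test between groups was made and no p-value is given. Genes at least 2-fold and at least 4-fold apart were counted as a description of these arrays. The 38 gene lists (746 distinct genes, 644 with a probe set of their own, 92 in more than 1 list) were fixed from general knowledge before the data were examined. They cover NK cell biology, cell state, metabolism and the other cell types a liver sort could hold. Published work on liver NK cells, this study's own included, is part of that knowledge, so the lists of resident and circulating NK markers are not independent evidence of their direction. For each list with at least 3 detected members the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these arrays and is not a test of the populations. Genes below the limit on 1 array entered the medians at their bound.

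Named genes followed a rule fixed at the same time. It took every sort marker, the 10 largest ratios per direction among genes above the limit on both arrays and the 5 largest bounds per direction. It also took up to 4 detected members per list with the largest ratio. Genes named outside this rule are marked as chosen after their values were seen. Where another detected probe set of a named gene went the other way by over 1.5-fold this is said. In addition to the planned lists, 9 lists were written after the main results had been seen; they are used only in the closing section.

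Noise between probe sets was used as a partial measure of technical error. Over 4091 genes with at least 2 probe sets above both limits, the log2 ratio had an SD of 0.32 between probe sets of the same gene, from 0.40 among the dimmest of them to 0.23 among the brightest. This spread leaves out differences between cell preparations, labellings and mice. The steps were tested on simulated data made for this comparison from the arrays' own mean values, with that noise and 200 changed genes. Of genes changed 2-fold 46% were recovered at the 2-fold threshold, of those changed 3-fold 86%, of those changed 4-fold 94% and of those changed 8-fold 100%. Of 9659 unchanged genes 22 passed 2-fold. Of 200 lists of randomly drawn genes, 12 fell outside the central 95% of matched random lists.

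Alternatives fixed beforehand were centring on the median, quantile normalization, intensity-dependent centring by lowess (fraction 0.3), the mean over all detected probe sets of a gene, leaving out probe sets with IDs ending in _x_at or _s_at, no detection limit, limits at the array median or the 99th percentile, and an offset equal to the limit. Scaling to the spike-in controls and leaving out genes of other cell types were added after the data had been seen. Replicates could not be left out, since there were none. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.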

Results

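Gene expression was profiled in DX5- NK1.1+ CD3- and DX5+ NK1.1+ CD3- cells sorted from mouse liver, with 1 array for each population. NK cells are innate lymphocytes that kill target cells and secrete cytokines. The study set out to describe how the DX5- and DX5+ subsets differ in expressed genes. The median intensity over 45101 probe sets was 70.3 on the DX5- array and 78.0 on the DX5+ array. Of 18193 named genes, 8846 were above the detection limit on both arrays, 653 on the DX5- array only and 471 on the DX5+ array only. Because neither population had a replicate, no ratio has a spread between samples and none was tested; all folds describe these arrays. Within genes, probe sets differed in log2 ratio with an SD of 0.32, which covers probe noise only.

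The ratio of 3' to 5' intensity was 1.73 for the actin control on the DX5- array and 1.62 on the DX5+ array. For the Gapdh control it was 0.782 and 0.766. Of the 18 spike-in control probe sets added at hybridisation, 18 were lower on the DX5- array, with a median log2 ratio of -0.22. The log2 intensities of genes above both limits had a Pearson correlation of 0.947 across genes, which are not independent replicates. Of these genes, 76.9% differed by less than 1.5-fold, and their median log2 ratio was -0.015.

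The sort markers were examined first. Itga2, which encodes the chain recognised by DX5, read 29.0 on the DX5- array and 105 on the DX5+ array; both values were below the limits, so no fold is given. Klrb1c, the NK1.1 gene, had no probe set listed for it alone. Transcripts of the CD3 complex, the signalling part of the T cell receptor, were higher in DX5- cells although both sorts excluded surface CD3. Cd3g was 13.1-fold higher (14036 against 1072), Cd3d 3.33-fold higher (2607 against 782) and Cd3e at least 3.49-fold higher. Cd247, the zeta chain that NK cells also use for their own receptors, was 2.12-fold lower in DX5- cells. The 4 detected sort markers had a median log2 ratio of 1.77.

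Across the transcriptome, 356 genes were at least 2-fold higher and 550 at least 2-fold lower in DX5- cells, together 9.09% of 9970 detected genes. At 4-fold the counts were 63 higher and 87 lower. The genes with the largest ratios in DX5- cells, measured on both arrays, were Cd3g, Gzmc (12.3-fold, a granzyme of killer cell granules), Asb2 (12.1-fold), Sema6d (11.6-fold, a semaphorin), B3galt5 (11.2-fold), Trgv1 (10.9-fold, a T cell receptor gamma variable segment), Cxcr6 (9.62-fold, the receptor for CXCL16), Klra5 (9.15-fold), Gm36723 (8.91-fold) and Jag1 (8.27-fold, a Notch ligand). Creb3l1, Itga1, Cd200r1, Gpr34 and Ccdc136 were above the limit in DX5- cells only, by at least 9.73, 9.33, 5.88, 5.61 and 5.08-fold. The genes with the largest ratios in DX5+ cells, measured on both arrays, were Phactr3 (13.7-fold), Cma1 (13.6-fold, a chymase), Fcgr2b (10.6-fold, the inhibitory Fc gamma receptor), Myb (10.5-fold, a transcription factor), Il6 (10.2-fold), Serpinb9b (9.79-fold), Dhrs3 (9.41-fold), Rgs16 (9.06-fold), Gng11 (8.67-fold) and Klra8 (8.55-fold, the activating receptor Ly49H). S1pr5, As3mt, Khdc1a and Dixdc1 were above the limit in DX5+ cells only, by at least 16.9, 9.14, 8.38 and 6.86-fold, as was Elovl7, which read 908.5 in DX5+ cells and 68.7 in DX5- cells.

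These counts have no replicate check. Of the 278 genes past 2-fold with several probe sets above both limits, 259 had all of those probe sets in the same direction. When arrays were scaled to the spike-in controls, a choice made after the data were seen, 63.1% of the genes past 2-fold were higher in DX5- cells (623 higher, 364 lower) against 39.3% as deposited, and at 4-fold 88 were higher and 55 lower. With the detection limit at the 99th percentile 52.5% were higher (298 higher, 270 lower), and at 4-fold 53 were higher and 36 lower. More genes stayed lower than higher at 2-fold with median centring (492 lower, 402 higher), quantile normalization (479 and 406) and intensity-dependent centring (477 and 406). Among the alternatives, the majority turned only with spike-in scaling and with the limit at the 99th percentile. The stricter limit was 341 on the DX5- array and 159 on the DX5+ array. Such unequal floors remove more lower than higher genes by construction, so that turn says little about the cells.

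**Figure D1:**
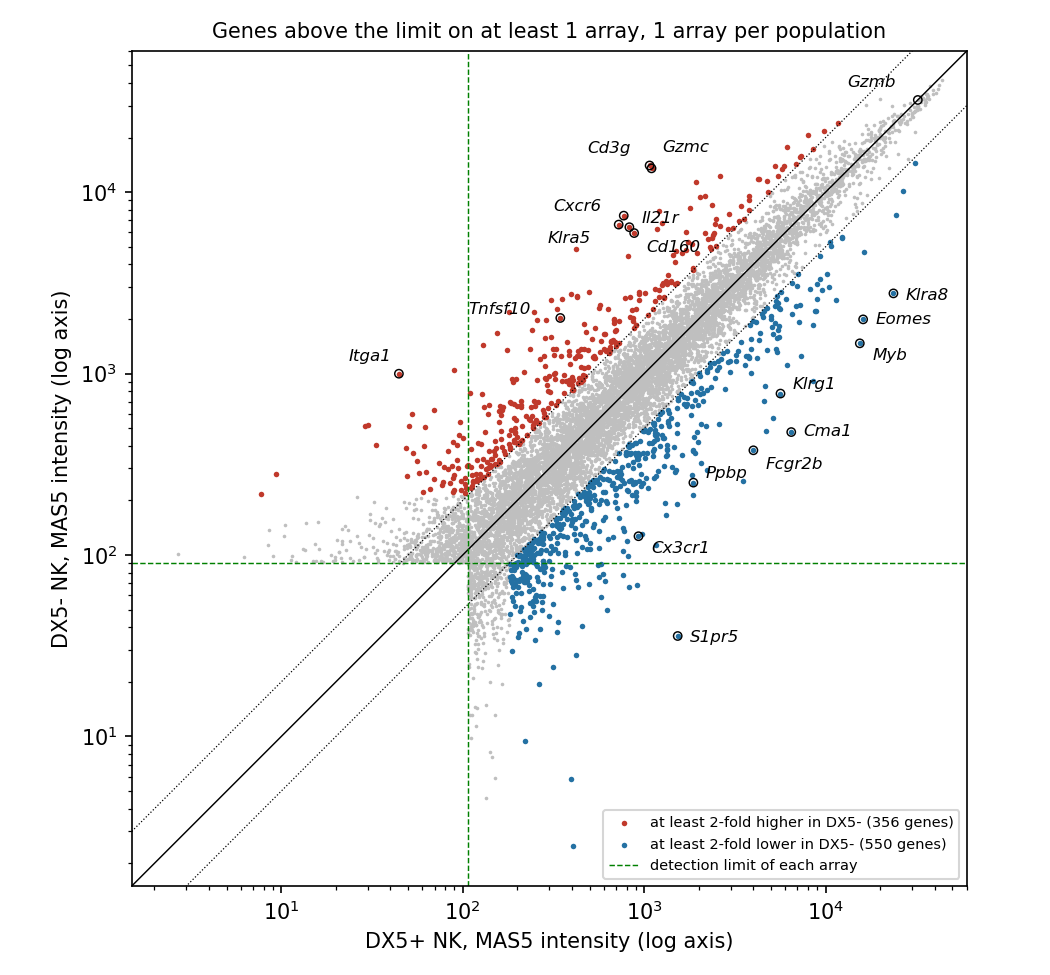
MAS5 intensity on the DX5- array (vertical, log axis) against the DX5+ array (horizontal, log axis) for the 9970 genes detected on at least 1 array; each point is a gene, the solid line marks equal intensity, dotted lines mark 2-fold, and dashed lines mark the detection limits (90.9 and 107). Red points are the 356 genes at least 2-fold higher and blue points the 550 at least 2-fold lower in DX5- cells, with Itga1 and S1pr5 each above the limit on 1 array only.

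Markers of liver-resident NK cells and type 1 innate lymphoid cells (ILC1) were higher in DX5- cells. Of 17 detected members 12 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.43. Itga1, the collagen-binding integrin alpha 1 (CD49a), read 999 in DX5- cells and 44.5, below the limit, in DX5+ cells. Cxcr6 read 7425 against 772, the cytokine receptor gene Il21r was 7.73-fold higher and Tmem176b was 6.98-fold higher. Tnfsf10, which encodes the death ligand TRAIL, was 5.87-fold higher, and Cd200r1, an inhibitory receptor gene, at least 5.88-fold higher. The list median lay above all 10000 matched random lists, whose central 95% ran from -0.21 to 0.21.

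Markers of mature circulating NK cells were lower in DX5- cells. Of 16 detected members 12 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.91. Eomes, a T-box transcription factor of NK cells, read 1991 in DX5- cells and 16107 in DX5+ cells, an 8.09-fold difference. S1pr5, a sphingosine 1-phosphate receptor used in tissue exit, was at least 16.9-fold lower. Cma1 was 13.6-fold lower and Khdc1a at least 8.38-fold lower. The list median lay below all 10000 matched random lists.

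Genes of tissue residency and of tissue exit lay on opposite sides as well. Of 22 detected genes of the residency program described in memory T cells, 10 were at least 2-fold higher and 1 at least 2-fold lower in DX5- cells (median 0.81, above all 10000 random lists). Beside Cxcr6 and Itga1 they included Cdh1 (6.85-fold, E-cadherin) and P2rx7 (6.10-fold, an ATP-gated channel). Itgae, the CD103 integrin chain of many resident T cells, was the exception, at least 2.92-fold lower. Of 16 detected genes of the exit and recirculation program, 11 were at least 2-fold lower and 0 higher (median -1.48, below all random lists). Among them Cx3cr1 was 7.33-fold lower and Klrg1, an inhibitory receptor of mature NK cells, 7.27-fold lower. These programs share 6 and 9 genes with the marker lists above, so they are not separate evidence.

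Transcription factors of NK cells and ILCs went both ways. Of 44 detected, 7 were at least 2-fold higher and 10 at least 2-fold lower in DX5- cells (median 0.075, mean -0.054, percentile 85.3 of random lists). Ikzf2 (Helios) was 5.46-fold higher and Bcl11b 4.66-fold higher. Myb was 10.5-fold lower and Eomes 8.09-fold lower. Tbx21, the T-bet gene, read 9475 against 7704, and Nfil3 9359 against 8982; both were chosen after their values were seen.

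Receptor genes differed in both directions within each family. Among Ly49 genes, the lectin-like receptors for MHC class I, Klra5 (Ly49E) was 9.15-fold higher in DX5- cells. Klra8 was 8.55-fold, Klra7 3.42-fold and Klra17 at least 2.14-fold lower. Only 4 Ly49 genes were detected with a probe set of their own, and near-identical paralogues can cross-hybridise, so these ratios are uncertain. Of 24 other NK receptors 5 were at least 2-fold higher and 4 at least 2-fold lower (median 0.62, above all random lists). Cd160 was 6.75-fold higher, the checkpoint receptor gene Ctla4 3.05-fold higher and Lag3, another, at least 4.90-fold higher, and Klrg1 7.27-fold lower.

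Effector genes included members far apart in both directions. Of 22 detected genes of cytotoxic granules and death ligands, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.19, percentile 1.26; with spike-in scaling the median was 0.032). Gzmc was 12.3-fold, Tnfsf10 5.87-fold and Gzmf at least 3.76-fold higher in DX5- cells, and Serpinb9b, a member of the granzyme inhibitor family, was 9.79-fold lower. Gzmf read 402 in DX5- cells beside 13530 for Gzmc. Cross-hybridisation between granzyme probe sets was not tested, so these 2 ratios may not be independent. Gzmb, chosen after its values were seen, read 32230 against 32238, and Prf1, the perforin gene, chosen likewise, 3108 against 8978. Of 21 cytokines and chemokines 8 were at least 2-fold higher and 3 at least 2-fold lower (median 0.33, percentile 99.8). Ltb (lymphotoxin beta) was 5.37-fold and Il2 at least 4.74-fold higher, while Il6 was 10.2-fold and Ccl9 4.29-fold lower. Ifng, chosen after its values were seen, read 14891 against 11958.

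Genes of migration and adhesion were split. Of 16 chemokine and lipid migration receptors, 3 were at least 2-fold higher and 5 at least 2-fold lower (median -0.60, percentile 0.010). Cxcr6 stood at the high end. S1pr5, Cx3cr1 and S1pr1 (4.89-fold) stood at the low end. Of 23 integrin and adhesion genes, 3 were at least 2-fold higher and 6 at least 2-fold lower (median -0.28, percentile 0.13). With the limit at the 99th percentile the median was 0, the log2 ratio assigned where a bound fell on the wrong side. Itga1 was higher, and Itgam (5.73-fold, CD11b), Itga4 (3.32-fold) and Itgae were lower in DX5- cells.

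Cytokine receptors showed no common shift. Of 33 detected, 7 were at least 2-fold higher and 5 at least 2-fold lower (median -0.047, mean 0.046, percentile 30.7). Il21r was 7.73-fold and Il12rb1 3.80-fold higher, whereas Il18r1 was 4.09-fold and Csf2rb 3.86-fold lower. The TNF and death receptor families had a median of 0.25 (percentile 98.7), or 0.13 with the limit at the 99th percentile and 0.47 with spike-in scaling. Of these 18 genes 6 were at least 2-fold higher and 0 at least 2-fold lower. The higher genes included Tnfsf10, Ltb, Tnfrsf18 (2.88-fold, GITR) and Tnfrsf25 (at least 2.82-fold).

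**Figure D2:**
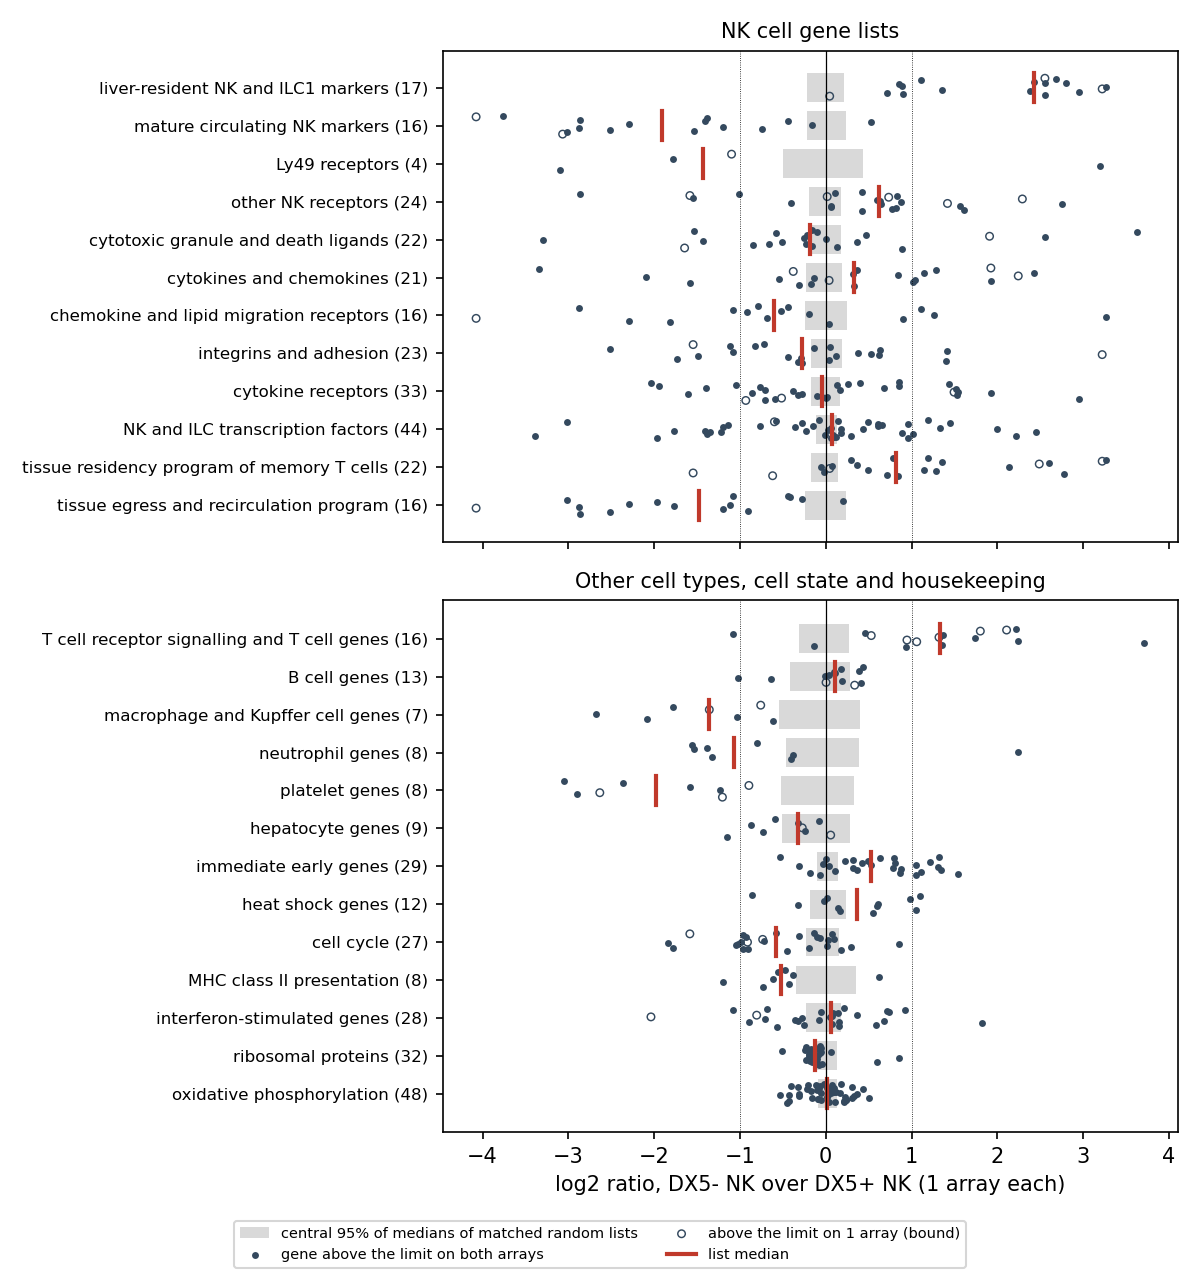
Log2 ratio of DX5- over DX5+ cells (horizontal) for detected members of 25 of the gene lists (vertical, number of detected genes in brackets), with 1 array per population; filled points are genes above the limit on both arrays, open points are bounds, red bars are list medians and grey boxes the central 95% of medians of 10000 matched random lists. The resident NK list (median 2.43) and the circulating NK list (-1.91) lie on opposite sides, and 8 of 8 platelet genes lie below 0; the small shifts of cytotoxic and ribosomal genes change sign with spike-in scaling.

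Lists of genes that report cell state were examined next. Of 29 immediate early genes, which respond within minutes to stimulation or handling, 8 were at least 2-fold higher and 0 at least 2-fold lower in DX5- cells (median 0.53, above all random lists). Junb was 2.90-fold, Egr2 2.53-fold, Atf3 2.49-fold and Fosb 2.47-fold higher. Of 12 heat shock genes 10 were within 2-fold and 2 at least 2-fold higher, Hspa1b (2.14-fold) and Hsph1 (2.07-fold), with a median of 0.36 at percentile 99.7. Dnajb1 was 1.97-fold higher and Bag3 1.81-fold lower. Of 27 cell cycle genes 0 were at least 2-fold higher and 5 at least 2-fold lower (median -0.58, below all random lists), among them Kif23 (3.57-fold) and Stmn1 (3.43-fold). The cell cycle median was -0.33 without _x_at and _s_at probe sets, -0.40 with the limit at the array median and -0.70 with no limit. With the limit at the 99th percentile it was 0, the log2 ratio assigned where a bound fell on the wrong side. That 0 does not show that the shift vanished. Of 28 interferon-stimulated genes 1 was at least 2-fold higher, Igtp (3.53-fold), and 2 were at least 2-fold lower, Usp18 (at least 4.10-fold) and Gbp3 (2.11-fold); the median was 0.058 and the mean -0.048, at percentile 76.6. Among 8 MHC class II presentation genes Ctss (2.29-fold) was the 1 gene at least 2-fold lower, with a median of -0.52 at percentile 0.37. The lists of dendritic cell genes (median -0.52, 2 of 8 at least 2-fold lower) and macrophage genes (median -1.36, 5 of 7), markers of cells that present antigen, also had negative medians. The list of B cell genes, whose cells present antigen too, did not (median 0.11, percentile 83.8).

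Genes of T cells, the CD3 chains among them, were higher in DX5- cells. Of 16 detected, 10 were at least 2-fold higher and 1, Cd247, at least 2-fold lower (median 1.34, above all random lists; 0.78 with the mean over probe sets). These 16 include the 4 detected sort markers given above, so the count does not stand apart from them. Camk4 was 4.73-fold, Bcl11b 4.66-fold and Trgv4, another gamma variable segment, at least 4.31-fold higher. Several of these genes are also transcribed in ILCs. ILC2 genes (5 detected, median -0.22, percentile 14.4) and ILC3 genes (4 detected, median 0.018, percentile 59.3) lay inside the range of random lists. Arg1, at least 2.80-fold higher, and Klrg1 were the ILC2 genes past 2-fold, and Ahr, 2.28-fold higher, the ILC3 gene.

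The lists of platelet and myeloid cell genes had negative medians, but only among platelet and detected macrophage genes were most members at least 2-fold lower in DX5- cells. Of 8 platelet genes 7 were at least 2-fold lower (median -1.98, below all random lists; -0.86 with the limit at the 99th percentile), including Clec1b (8.26-fold), the chemokine genes Ppbp (7.45-fold) and Pf4 (5.16-fold), and Gp1bb (at least 6.20-fold). Of 19 macrophage and Kupffer cell genes on the array 7 were detected; Clec4f, C1qa, C1qb, Timd4 and Cd163, chosen after their values were seen, were among those below the limit on both arrays. Of the 7 detected genes 5 were at least 2-fold lower (median -1.36, below all random lists), including Lyz1 (6.40-fold) and Mpeg1 (4.25-fold). Of 8 neutrophil genes 4 were at least 2-fold lower, such as Ngp (2.94-fold) and S100a9 (2.90-fold), and Mmp9 was 4.74-fold higher (median -1.07, percentile 0.020). Dendritic cell genes (8 detected, 2 at least 2-fold lower, median -0.52, percentile 1.12) and basophil and mast cell genes (4 detected, Cpa3 4.65-fold lower, median -0.72, percentile 2.30; -1.49 with no detection limit) followed. The medians of these lists thus lay on the same side as that of the circulating NK markers, although most dendritic, basophil and mast cell genes were within 2-fold.

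Lists of other liver cells and of basic metabolism had medians nearer 0. B cell genes (13 detected, median 0.11, percentile 83.8), plasma cell genes (6, -0.18, 23.2), hepatocyte genes (9, -0.32, 13.3), endothelial genes (9, -0.42, 5.21) and erythroid genes (4, -0.0082, 57.6) had medians inside the central 95% of random lists. Among the endothelial genes Fcgr2b (10.6-fold) and Clec1b (8.26-fold) were lower in DX5- cells, and the list's median was -1.26 with the limit at the 99th percentile. Alb, the albumin gene of hepatocytes, read 836 against 1262. Only 2 stellate cell and fibroblast genes were detected, Ecm1 and Des, at least 1.86-fold and 1.56-fold lower in DX5- cells. Genes of oxidative phosphorylation had a median of 0.017 and a mean of -0.0016, with 0 of 48 past 2-fold. Glycolysis genes had a median of 0.063 and a mean of -0.085, with 1 of 16 past 2-fold, Pfkfb3, 2.45-fold lower. Housekeeping genes (13 detected, median -0.13, percentile 5.91) and ribosomal protein genes (32 detected, median -0.12, percentile 0.77) had 0 members past 2-fold; with spike-in scaling their medians were 0.089 and 0.093. The erythroid list also had a mean of the other sign, 0.055.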

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

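With 1 array per population, no replicate could be left out and no paired fit exists. No paired analysis was possible because each population has 1 array. Median, quantile and intensity-dependent centring, the mean over probe sets, leaving out _x_at and _s_at probe sets and a limit at the array median kept the counts at 2-fold and 4-fold within 1.5 times. Leaving out genes of other cell types, added after the data were seen, left 9893 of 9970 detected genes (355 higher and 528 lower at 2-fold); so few genes were removed that the counts had little room to move, which says nothing about their stability. Without a detection limit 1888 genes were at least 2-fold higher and 2838 lower in DX5- cells, and 674 and 1135 at 4-fold; dim probe sets make up the increase by construction. With the limit at the 99th percentile (341 on the DX5- array, 159 on the DX5+ array) 270 genes were lower at 2-fold and 36 at 4-fold, against 298 and 53 higher. The higher floor on the DX5- array removes more lower than higher genes by construction. With the limit added as an offset, which shrinks ratios of dim genes, the counts were 216 and 350 at 2-fold and 38 and 42 at 4-fold. Spike-in scaling, added after the data were seen, moved the median log2 ratio of all genes above both limits from -0.015 to 0.20 and gave 623 higher and 364 lower at 2-fold, and 88 higher and 55 lower at 4-fold, so the majority turned at both. The median of the resident NK list was 1.78 with the mean over probe sets, 2.03 with the offset and 2.64 with spike-in scaling, against 2.43. The median of the circulating NK list was -2.25 with the mean over probe sets, -1.69 with no limit, -1.53 with the limit at the array median, -1.39 at the 99th percentile, -1.73 with the offset and -1.69 with spike-in scaling, against -1.91. Spike-in scaling turned the medians of the cytotoxic list (0.032) and the ribosomal protein list (0.093); a common shift leaves their rank among random lists as it was. Medians of cytokine receptors, interferon-stimulated, plasma cell, ILC3, erythroid, housekeeping and oxidative phosphorylation genes took the other sign under at least 1 alternative. Among the values of named genes under the alternatives 1336 stayed within the SD between probe sets, 149 moved by more and 0 turned where the ratio was past 2-fold. Much of this tally was fixed in advance. Median centring and spike-in scaling shift all ratios by a common amount below that SD, so their 150 values each had to stay. Lower limits cannot move a gene already above both limits. The tally is therefore no measure of stability. Ratios of genes near the limits, where probe sets of a gene differed with an SD of 0.40, are the least certain.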

Other observations

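The tests of the T cell and immediate early patterns, the B cell comparison and the 9 further gene lists were chosen after the main results had been seen; the test on the second platelet list was written before its values were.

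The percentiles of the further lists describe genes grouped after the main results had been seen, so they do not show that a group differs. This holds for the second platelet list too, for which only the prediction came before its values. Of 15 detected genes of cytokine signalling feedback and survival, 5 were at least 2-fold higher, 9 within 2-fold and 1 at least 2-fold lower (median log2 ratio 0.41, percentile 99.9 of matched random lists). Socs2 and Cish, feedback inhibitors induced by STAT5, were 6.44-fold and 4.39-fold higher, Socs1 2.81-fold and the kinase gene Pim3 2.80-fold higher, and Socs4 was 2.48-fold lower. Proximal signalling genes had a median of 0.10 (percentile 81.3), with 5 of 21 at least 2-fold higher, among them Plcg1 (4.84-fold), Vav3 (3.84-fold) and Zap70 (2.58-fold), and 1, Cd247, 2.12-fold lower. In the SLAM family and its adaptors (10 detected, 0 at least 2-fold higher, 2 lower, median -0.27, percentile 4.71) Sh2d1a, the SAP adaptor gene, was 7.61-fold lower. Purinergic genes (9 detected, 2 at least 2-fold higher, 1 lower) had a median of 0.41 at percentile 98.6 of random lists, with P2rx7 6.10-fold higher and P2ry14 4.58-fold lower.

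Notch pathway genes went both ways (17 detected, 4 at least 2-fold higher, 2 lower, median 0.026, percentile 67.2). The ligand Jag1 was 8.27-fold and Dtx1 3.32-fold higher, while Nrarp, itself a Notch target, was 3.50-fold lower. Among semaphorins, plexins and ephrins (14 detected, 1 at least 2-fold higher, 5 lower, median -0.24, percentile 10.9) Sema6d was 11.6-fold higher, and Plxnc1 (7.94-fold) and Sema4f (4.52-fold) were lower. The cadherin and junction genes Cdh1 (6.85-fold), Cdh17 (at least 3.93-fold) and Epcam (3.06-fold) were higher and Tjp1 was at least 2.87-fold lower (7 detected, 3 at least 2-fold higher, 1 lower, median 0.27, percentile 91.8). Of 7 retinoid genes Dhrs3 was 9.41-fold lower and 0 others passed 2-fold (median -0.41, percentile 3.96).

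Platelet genes were lower on the DX5- array, and 1 hypothesis is that the DX5+ sort held more platelets or platelet RNA, since DX5 binds an integrin chain that platelets also carry; the NK1.1 gate would remove free platelets but not platelets bound to NK cells. A second platelet list with no gene of the first had a median log2 ratio of -0.57 over 19 detected genes (percentile 0.030 of random lists). Of these, 6 were at least 2-fold lower, 13 within 2-fold and 0 at least 2-fold higher. The result met the prediction set for this hypothesis. The macrophage, neutrophil, basophil and mast cell, and dendritic cell lists also lay below the 2.5th percentile (0, 0.020, 2.30 and 1.12). The second list therefore does not single out platelets. A loss of purity in the DX5+ sort that raised every other cell type alike would move the B cell median too. That median was 0.11, beside -1.98 for platelet genes. The B cell list was picked after the main results had been seen, so this comparison gives no verdict on purity. That comparison cannot address an uneven admixture of other cells, which stays open. Macrophage (-1.36), neutrophil (-1.07), basophil and mast cell (-0.72) and dendritic cell (-0.52) medians were also lower on the DX5- array, although the NK1.1 gate would remove such cells. So were the endothelial (-0.42) and hepatocyte (-0.32) medians, inside the range of random lists. The Kupffer cell genes C1qa, C1qb and Clec4f and the mast cell genes Fcer1a and Ms4a2, all chosen after their values were seen, were below the limit on both arrays. The 7 detected macrophage genes and the 4 detected basophil and mast cell genes were all lower on the DX5- array. Among them Adgre1, Csf1r and Mcpt8 were above the limit on the DX5+ array only, so by construction their ratios could not be positive. Itgb3, an integrin chain abundant in platelets that is in neither platelet list and was chosen after its values were seen, was 2.66-fold higher in DX5- cells, while Ppbp read 251 against 1868. Expression of such genes by DX5+ NK cells themselves was not tested and stays open.

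The CD3 genes Cd3d, Cd3e and Cd3g and the gamma variable genes Trgv1 and Trgv4 were higher on the DX5- array. A hypothesis is that T cells or NKT cells left in the DX5- sort contribute, although the gate removed cells with surface CD3. Trac, Trbc1, Trbc2 and Trdc, constant genes of the alpha, beta and delta chains, had no probe set listed for them alone. They were therefore not measured. Of 7 T lineage genes seldom used by NK cells, 3 were above the limit on the DX5- array (Cd5, Cd6 and Cd8a) and 1 on the DX5+ array (Cd6), and Cd4, Cd8b1, Themis and Cd40lg were not on the DX5- array. Neither outcome decides, because the sensitivity of each probe set is unknown and Cd5, Cd6 and Cd8a read only 155, 212 and 206 there. Transcription of these genes by DX5- NK cells, as known for ILCs, stays open as the biological alternative.

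The median of immediate early genes was higher on the DX5- array, with 8 of 29 at least 2-fold higher. A scaling bias of bright probe sets is argued against, since the median of 0.53 lay above random lists matched on mean expression (central 95% from -0.11 to 0.15). Intensity-dependent centring left the median at 0.50, above the central 95% of random lists (-0.14 to 0.12). Because those lists were already matched on brightness, the centring repeats that comparison and adds little. Whether stress during isolation could contribute is open: the heat shock median was 0.36, but 10 of 12 of these genes were within 2-fold and Bag3 was 1.81-fold lower, and with 1 array per population handling and population cannot be told apart. Stimulation of DX5- cells in the liver stays open.

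Xist and the Y-linked genes Kdm5d, Uty and Eif2s3y were above the limit on both arrays, at 1253 against 807, 382 against 427, 548 against 694 and 3239 against 2698 (list median 0.052, percentile 58.7); a second detected probe set of Uty went the other way, 264 against 166.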
